A study of Homo sapiens with 4 samples.

How the data were processed

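Drop-seq was run on human CD34+ cells mobilized with G-CSF, all from 1 donor, after 2 hours of culture on Delta1ext-IgG, an immobilized Notch ligand. Per the labels, 2 droplet runs were made in normoxia at 10 µg/mL of ligand and 2 in hypoxia at 5 µg/mL. The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization, and the authors deposited each library separately. Per the submitters' processing notes, STAR 2.5.4a, Seurat 3.2.0 and the hg19 build were used, with no role or order stated. The annotation and the counting tool are not given in the sources used here, so reads shared between near-identical genes cannot be assigned. This holds for HSPA1A and HSPA1B, for CCL4 and CCL4L2, and for HSP90AA1 and its pseudogenes, and other named genes were not searched for close copies. The available reference annotation was of another build, so no coordinates are printed, and it was used only to leave out 85 genes (XIST, TSIX and Y-linked genes) before any test.

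The 4 matrices listed 4000 and 3900 barcodes in normoxia and 3000 and 3500 in hypoxia, 14400 in all, with 25516 to 30023 gene symbols per library and 36287 in their union. Barcodes with at least 200 genes and at most 20% of UMIs from mitochondrially encoded genes were kept as cells. That left 1987 and 1122 cells in normoxia and 1954 and 2027 in hypoxia, 7090 in all. The kept cells held 96.1% and 94.2% of the UMIs of their libraries in normoxia and 98.1% and 97.6% in hypoxia. Doublets were called per library with scrublet in scanpy 1.11.5, which marked 5, 12, 12 and 11 cells, 40 in all. They were left out of the clustering but kept in the library sums, and the sums without them were an alternative. Counts of the libraries were compared by a chi-square statistic per gene over genes with an expected count of at least 5. It was 4.26 for the normoxia pair and 4.09 for the hypoxia pair, against 11.4 to 15.1 between conditions, so no pair matched within sampling noise and each library was counted once.

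UMI counts were summed over the kept cells of each library and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM factors (1.02 and 1.08 in normoxia, 0.975 and 0.934 in hypoxia) and filterByExpr by condition. This left 16449 genes and 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are TMM-adjusted UMI CPM, given as mean ± SD over the 2 libraries of a condition, and log2 fold changes are hypoxia over normoxia ± SE. The edgeR test gives no SE, so it was derived as the absolute log2 fold change divided by the square root of the F statistic. It is therefore an approximation. Intervals and floors (3 counts) cover counting error only.

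Gene lists, 31 in all, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. With an estimated correlation camera has only the 2 residual degrees of freedom, so it had little power to call any list here. Named genes were chosen by a rule. It took the 10 genes with the largest change in each direction among those called, with at least 50 CPM in the higher condition and both libraries of one condition above both of the other. It added up to 4 members per list with the lowest adjusted p and 20 genes fixed by name, and passed over clone names and mitochondrially encoded genes among the 10. Within clusters it took 3 genes in each direction. Genes outside the rule are said to be chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

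For clustering, counts per cell were log-normalized, genes called between the conditions were left out, and 2000 variable genes were scaled within each library. Leiden clustering at resolution 1 on 20 principal components and 20 neighbours gave 11 clusters of 7050 cells (igraph 0.11.9, scikit-learn 1.9.0). A cluster was named only with at least 3 markers of a fixed list at 2-fold or more and 30 CPM, and with more of them among its 10 leading genes than of any other list. That scoring rule was set after the data were seen. Tests within classes were planned for classes with at least 50 cells in every library. No named class alone reached that, so clusters 1 to 7 were tested by number and the 3 named classes were pooled. The difference in response was tested as an interaction with cluster 1, the cluster with the most cells, with library as a block. Shares of cells were compared by an exact two-sided permutation test, which with 2 libraries against 2 cannot go below p = 0.333, and carry exact Clopper-Pearson 95% intervals per library. Genes per cell were counted after thinning each cell to 1000 UMIs, which left out 1579 shallower cells.

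The gene test was tested on simulated counts for hypoxia against normoxia, with 200 of 16301 genes changed, all drawn from genes with a mean of at least 20 CPM. It recovered 25.4% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, and 8 of its 153 calls (5.23%) were false. In the same comparison camera recovered 5 of 5 lists of 15 genes raised 1.5-fold and called 0 of 20 unchanged lists. The simulated genes were drawn independently, so false calls for lists whose members move together were not tested. In the data the estimated correlation was 0.644 for nuclear respiratory chain genes, 0.958 for mitochondrially encoded mRNAs and 0.898 for cytosolic ribosomal protein genes. The interaction test of cluster 6 against cluster 1 recovered 87% of 100 genes changed 3-fold among 8690, with 8 false calls. Its changed genes were drawn from those with at least 100 CPM in cluster 1. Recovery of genes below these levels was not tested. Each simulation also gave all genes 1 shared dispersion, close to the common value of 0.0133 in the data. Recovery and false calls where the spread varies from gene to gene were therefore not tested.

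Alternatives covered RLE size factors, library size without TMM factors, and leaving out mitochondrially encoded and ribosomal protein genes. They also covered DESeq2 1.42.0, limma-voom, no filter on low counts, other cell filters, removal of doublets, thinning of library sums or of single cells, the replicate number as a block, and each library left out in turn. Where 1 library was left in a condition, its spread was taken to equal that of the other condition. Removal of a cluster led by stress genes, a crossed block, the tests by cluster number and the counts in barcodes with under 150 UMIs were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9 did the rest.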

Results

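Single-cell transcriptomes of CD34+ hematopoietic stem and progenitor cells were collected after a short culture on a Notch ligand, to compare normoxia with hypoxia. Notch receptors respond to Delta1 by releasing an intracellular domain that switches on target genes such as HES1. Each condition had 2 libraries, which the labels call technical replicates, so p-values measure only the spread between droplet runs and not between cultures or donors. Oxygen, ligand dose (10 µg/mL in normoxia, 5 µg/mL in hypoxia) and experiment changed together, so each difference is one between these whole conditions. Kept cells held 5086322 and 1870541 UMIs in the normoxia libraries and 5455384 and 6094817 in the hypoxia libraries. The median cell had 2082 and 1349 UMIs in normoxia and 2426 and 2593 in hypoxia, and the median mitochondrial share was 3.11% and 3.07% against 4.13% and 3.64%.

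Hypoxia cells had less mRNA of the chaperone HSPA1A, of the immediate early genes FOS and JUN and of the Notch targets HES1 and HES4, and more mRNA of the HIF target EGLN3. Among genes that met the naming rule, with at least 50 CPM, the largest fall was in HSPA6, an inducible chaperone, from 77.5 ± 3.28 to 1.89 ± 1.07 CPM (log2 fold change -5.32 ± 0.27, edgeR adjusted p = 1.23e-09). VGF, a secreted neuropeptide precursor, fell by 3.61 ± 0.24 on the log2 scale, TIMP3, an inhibitor of metalloproteinases, by 2.80 ± 0.17, and MMP9, a gelatinase, by 2.83 ± 0.20. The largest rise was in DCUN1D3, a cullin neddylation regulator, from 27.1 ± 3.47 to 78.9 ± 7.83 CPM (1.57 ± 0.17, edgeR adjusted p = 1.5e-05). SAFB, a nuclear matrix protein, rose from 100.3 ± 16.3 to 242 ± 7.20 CPM, ARL6IP1 from 127 ± 9.43 to 294 ± 16.1, and RLF, a zinc finger protein, from 49.9 ± 3.90 to 121 ± 3.32. HEXIM1, an inhibitor of P-TEFb, had a log2 fold change of 1.30 ± 0.16. The other 5 genes of the rule that rose were ZBTB1 (1.30), SLC17A5 (1.24), CCNG1 (1.21), KRT18 (1.21) and OAZ2 (1.20).

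Of 16449 genes, 1113 were higher and 1133 lower in hypoxia by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 170 and 669 of these differed at least 2-fold. DESeq2 called 548 higher and 451 lower, and scaling by library size alone gave 514 and 1436, so that 26.4% of calls were higher in place of 49.6%, with the median of all genes moved by -0.13 on the log2 scale. Without hypoxia library 1 the counts were 328 and 412, without hypoxia library 2 they were 301 and 415, and thinning each cell to 1000 UMIs gave 445 and 582. Without normoxia library 1, 356 genes were at least 2-fold higher.

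**Figure D1:**
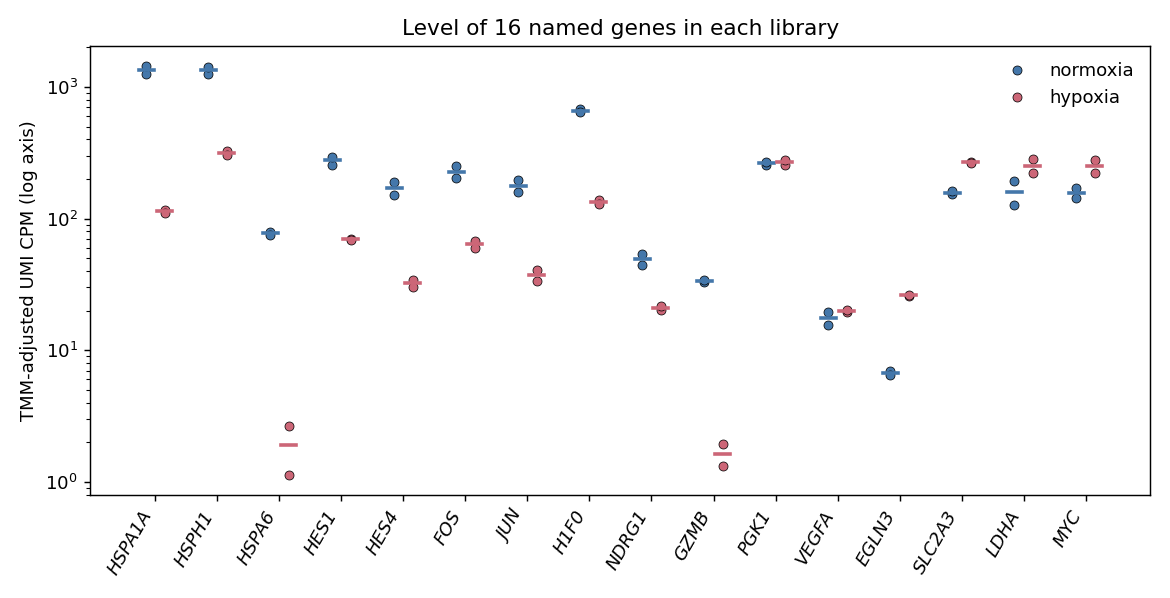
TMM-adjusted UMI CPM (log axis) of 16 named genes in each library, with normoxia in blue and hypoxia in red; points are libraries and bars are the means of 2. HSPA1A lies at 1348 CPM in normoxia and 114 in hypoxia, while PGK1 lies at 263 and 269.

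Heat shock genes, which encode chaperones induced by misfolded protein, were mostly lower in hypoxia. Of 14 members 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median log2 fold change of -1.21, a camera adjusted p = 4.85e-15 and an adjusted p = 0.431 with an estimated correlation. HSPA1A fell from 1348 ± 126 to 114 ± 4.08 CPM (-3.57 ± 0.16, edgeR adjusted p = 4.14e-10) and HSPA1B from 239 ± 8.16 to 38.9 ± 0.057 CPM, although reads of this near-identical pair cannot be assigned with certainty. HSPH1, a co-chaperone, fell from 1338 ± 121 to 313 ± 14.9 CPM (-2.09 ± 0.16) and HSPB1, a small heat shock protein, from 455 ± 46.2 to 137 ± 8.75 (-1.73 ± 0.14). Outside the list, the DNAJ family member DNAJA4 fell by 2.64 ± 0.19 on the log2 scale. The HSP90AA1 pseudogenes HSP90AA4P and HSP90AA5P had values of -2.71 and -2.87 but share sequence with HSP90AA1, which itself went from 6854 ± 331 to 2189 ± 83.2 CPM (chosen after its values were seen). For the list fry gave an adjusted p = 0.0171. The median mitochondrial share per cell, given above, was higher in both hypoxia libraries.

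Immediate early genes, the transcription factors and phosphatases induced within minutes of stimulation, were also mostly lower. Of 23 members 13 fell and 2 rose, JUND and SOCS3 (16 and 2 adjusted over the list alone; SOCS3 had an edgeR adjusted p = 0.0905 without hypoxia library 2), and the median log2 fold change was -0.89, with a camera adjusted p = 1.74e-10 and an adjusted p = 0.431 with an estimated correlation. EGR3 went from 99.9 ± 11.9 to 15.7 ± 2.18 CPM (-2.66 ± 0.18), JUN from 177 ± 26.4 to 37.2 ± 5.44 (-2.24 ± 0.16), FOS from 227 ± 32.1 to 63.7 ± 5.54 (-1.83 ± 0.15) and ATF3 from 48.5 ± 1.98 to 11.2 ± 0.24 (-2.13 ± 0.20), with edgeR adjusted p of 2.17e-06 or lower. JUND had a log2 fold change of 0.73 ± 0.14 and was chosen after its values were seen. For the list fry gave an adjusted p = 0.0456. Genes of the ATF4 and unfolded protein response, which handle amino acid shortage and endoplasmic reticulum stress, had 9 of 16 members falling and 0 rising, or 9 falling and 2 rising adjusted over the list alone. Their median was -0.49, with a camera adjusted p = 0.000953 and an adjusted p = 0.692 with an estimated correlation. The pro-apoptotic factor DDIT3 fell by 1.31 ± 0.18 on the log2 scale, the asparagine synthetase ASNS by 1.37 ± 0.25, the glutathione-degrading CHAC1 by 1.98 ± 0.37 and the amino acid transporter chain SLC3A2 by 0.82 ± 0.14.

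**Figure D2:**
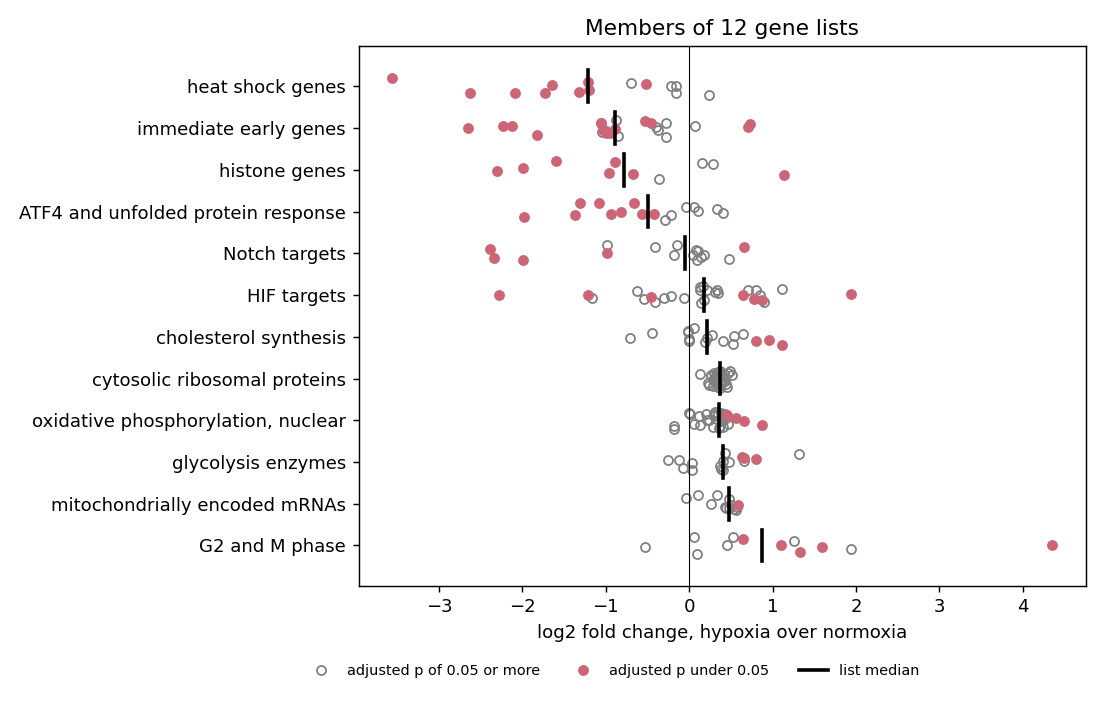
Log2 fold change (hypoxia over normoxia) of each tested member of 12 gene lists; filled points passed an adjusted p of 0.05 in edgeR, open points did not, and black bars are list medians. The heat shock median is -1.21 and the glycolysis median 0.41.

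Among Notch targets, HES4 and HES1, transcriptional repressors induced directly by Notch, were lower in hypoxia, where the ligand dose was also lower. HES4 went from 171 ± 28.9 to 32.4 ± 2.99 CPM (-2.39 ± 0.16, edgeR adjusted p = 2.97e-08) and HES1 from 277 ± 26.9 to 69.5 ± 0.78 CPM (-1.99 ± 0.14, edgeR adjusted p = 4.97e-08). The receptor NOTCH1 (181 ± 46.7 and 201 ± 0.57 CPM, edgeR adjusted p = 0.501) and the feedback regulator NRARP (4.53 ± 0.74 and 5.03 ± 0.14 CPM, edgeR adjusted p = 0.896) were not called. IL7R, the interleukin 7 receptor, fell from 7.18 ± 1.65 to 1.43 ± 1.22 CPM (edgeR adjusted p = 0.00686, 0.0833 without hypoxia library 1). MYC, a growth regulator, rose from 158 ± 18.8 to 251 ± 42.3 CPM (0.66 ± 0.15, edgeR adjusted p = 0.00775, 0.199 without hypoxia library 2). In all, 4 of 16 targets fell, TRIB2 (-0.98, chosen after its values were seen) among them, and 1 rose (4 and 2 adjusted over the list alone). The list's median was -0.051 and its mean -0.48. Camera gave an adjusted p = 0.164, but 0.0012 and 0.0239 without normoxia libraries 1 and 2, and 0.0471 and 0.00289 without hypoxia libraries 1 and 2; the medians were -0.23, -0.034, -0.071 and -0.027 in that order. Of 21 Notch pathway components, 2 rose and 1 fell (the same counts adjusted over the list alone): the coactivator MAML1 rose from 19.6 ± 1.44 to 39.7 ± 0.37 CPM (edgeR adjusted p = 0.00297). The glycosyltransferases RFNG (1.05 ± 0.25) and LFNG (-0.77 ± 0.20) moved in opposite directions. RFNG reached an edgeR adjusted p = 0.106 without hypoxia library 1, and LFNG 0.0516, 0.0599 and 0.111 without normoxia library 2, hypoxia library 1 and hypoxia library 2. With each cell thinned to 1000 UMIs they had 0.146 and 0.0979. The list's median was 0.25, with a camera adjusted p = 0.164, or 0.00709 with no filter on low counts.

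Targets of the hypoxia-inducible factors (HIF) went both ways. EGLN3, the prolyl hydroxylase that marks HIF for destruction, rose from 6.75 ± 0.34 to 26.2 ± 0.41 CPM (1.94 ± 0.26, edgeR adjusted p = 0.000101), and the glucose transporter SLC2A3 from 157 ± 5.00 to 269 ± 2.55 CPM (0.78 ± 0.13, edgeR adjusted p = 0.00117). BNIP3L, a mitophagy receptor, rose by 0.87 ± 0.17 on the log2 scale (edgeR adjusted p = 0.00267, 0.055 without hypoxia library 1). NDRG1, a stress-induced differentiation gene, instead fell from 49.2 ± 6.96 to 20.8 ± 1.06 CPM (-1.22 ± 0.19, edgeR adjusted p = 0.000593). Of 28 targets 4 rose and 3 fell (6 and 4 adjusted over the list alone), the others being WSB1 (0.65), P4HA2 (-2.28) and BHLHE40 (-0.46), chosen after their values were seen. The median was 0.17, with a camera adjusted p = 0.32, or 0.0268 with no filter on low counts. Several classical targets did not pass: VEGFA (17.5 ± 2.84 and 19.8 ± 0.46 CPM), ADM (2.13 ± 0.54 and 4.38 ± 3.45), BNIP3 (7.51 ± 0.73 and 13.7 ± 3.38) and ANKRD37 (5.43 ± 4.13 and 5.37 ± 0.90), as well as SLC2A1 (log2 fold change 0.81 ± 0.34) and PDK1 (0.18 ± 0.24). HIF1A itself had a log2 fold change of -0.39 ± 0.13 (edgeR adjusted p = 0.0571), and the heme oxygenase HMOX1 one of -0.027 ± 0.44.

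Enzymes of glycolysis had a median log2 fold change of 0.41, with 3 of 16 rising and 0 falling (10 and 0 adjusted over the list alone). Camera gave an adjusted p = 0.000647, and an adjusted p = 0.692 with an estimated correlation. TPI1 rose from 145 ± 28.9 to 256 ± 30.5 CPM (0.80 ± 0.15, edgeR adjusted p = 0.00277). ALDOA rose by 0.66 ± 0.14 on the log2 scale (edgeR adjusted p = 0.00457, 0.112 without hypoxia library 2) and LDHA, lactate dehydrogenase A, by 0.63 ± 0.18 (0.0234, but 0.0559 without normoxia library 2 and 0.257 without hypoxia library 2, 0.0668 scaled by library size alone and 0.0507 with cells thinned to 1000 UMIs). PGK1 stood at 263 ± 8.05 and 269 ± 15.8 CPM (edgeR adjusted p = 0.888), and PFKM at 2.36 ± 0.51 and 6.22 ± 0.30 CPM (0.0527).

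Respiratory chain genes encoded in the nucleus had a median log2 fold change of 0.36, with 4 of 32 rising and 0 falling (9 and 0 adjusted over the list alone); the median was 0.19 without hypoxia library 2. The succinate dehydrogenase subunit SDHA rose from 26.9 ± 3.37 to 50.3 ± 0.63 CPM (0.87 ± 0.18, edgeR adjusted p = 0.00429). NDUFB4 (0.56), UQCRH (0.66) and COX6C (0.46) also rose, but without hypoxia library 2 their edgeR adjusted p were 0.281, 0.25 and 0.419; without hypoxia library 1 NDUFB4 and COX6C had 0.0619 and 0.0931, and without normoxia library 2 UQCRH had 0.0872. Of 13 mitochondrially encoded mRNAs, 1 rose, MT-CO2 (0.58 ± 0.17), and 0 fell (7 and 0 adjusted over the list alone). MT-CO2 had edgeR adjusted p of 0.0871, 0.0758 and 0.315 without normoxia library 2, hypoxia library 1 and hypoxia library 2. The median of that list was 0.47, but 0.20 without normoxia library 2 (camera adjusted p = 0.148), 0.30 without hypoxia library 2 and 0.75 without normoxia library 1. Of 31 cytosolic ribosomal protein genes 0 passed edgeR's test and 0 adjusted over the list alone, with a median of 0.37, which was 0.60, 0.17 and 0.22 without normoxia library 1, normoxia library 2 and hypoxia library 2; the 4 lowest adjusted p, in RPL36, RPL15, RPL7A and RPL13A, ran from 0.0769 to 0.105. Camera gave adjusted p of 4.63e-06, 4.24e-05 and 1.51e-08 for these lists, and an adjusted p = 0.692 for each with an estimated correlation. The ribosomal median lay within the middle 95% of random lists matched on abundance, 0.223 to 0.406, at percentile 85.94, but at 98.25 without normoxia library 1. The mitochondrially encoded median lay above its range of 0.119 to 0.417, at percentile 99.7, but at 56.54 without normoxia library 2 and 87.43 without hypoxia library 2.

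Of 22 cell division genes of G2 and M phase only 12 passed the filter on low counts. Of these 5 rose and 0 fell in hypoxia (7 and 0 adjusted over the list alone). Their median was 0.88, with a camera adjusted p = 0.000517 and an adjusted p = 0.431 with an estimated correlation. The kinesin CENPE rose from 9.73 ± 1.13 to 23.9 ± 1.03 CPM (1.33 ± 0.25, edgeR adjusted p = 0.00225, 0.204 with each cell thinned to 1000 UMIs). The mitotic kinase AURKA had 1 UMI in normoxia and 37 in hypoxia, a ratio of 22.3 with an exact 95% counting interval of 3.76 to 904. It passed the filter through the hypoxia libraries alone. NUSAP1 (1.11 ± 0.30, edgeR adjusted p = 0.298 without hypoxia library 2), KIF20B (0.65 ± 0.18, 0.0996, 0.164 and 0.134 without normoxia library 1, hypoxia library 1 and hypoxia library 2) and MKI67 (1.59, chosen after its values were seen) also passed. Of 10 histone genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.79, a camera adjusted p = 5.62e-05 and an adjusted p = 0.431 with an estimated correlation. The linker histone H1F0 fell from 661 ± 29.5 to 134 ± 6.35 CPM (-2.31 ± 0.14), HIST1H4C from 463 ± 61.0 to 117 ± 8.04 (-1.99 ± 0.15) and HIST1H1E by 1.59 ± 0.21 on the log2 scale. The variant H2AFZ rose from 80.1 ± 16.1 to 180 ± 26.7 CPM (1.14 ± 0.16, edgeR adjusted p = 0.000198). For G2 and M genes the camera adjusted p was 0.0934 with library sums thinned to the smallest (median 0.44) and 0.158 with each cell thinned to 1000 UMIs (median 0.62). With cells thinned, NUSAP1 and KIF20B had edgeR adjusted p of 0.332 and 0.265. In S phase genes 1 of 20 rose and 0 fell (1 and 0 adjusted over the list alone), the ribonucleotide reductase RRM1 (1.16 ± 0.24, edgeR adjusted p = 0.00394, 0.169 with each cell thinned to 1000 UMIs), with a camera adjusted p = 0.91.

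Of 17 cholesterol synthesis genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.22. IDI1, an isomerase of the pathway, rose from 66.5 ± 7.28 to 142 ± 13.4 CPM (1.12 ± 0.15, edgeR adjusted p = 0.000115). HMGCR, the rate-limiting reductase, had 0.81 ± 0.21 (edgeR adjusted p = 0.0172, 0.242 without hypoxia library 2) and DHCR24 had 0.96 ± 0.30 (0.0395, but 0.308 and 0.0534 without hypoxia libraries 1 and 2). The list's camera adjusted p = 0.0187 became 0.104 without normoxia library 1 (median 0.14), 0.0632 with library sums thinned to the smallest, 0.0754 with each cell thinned to 1000 UMIs, and an adjusted p = 0.692 with an estimated correlation. Its median lay at percentile 86.83 of random lists matched on abundance.

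Among stem and progenitor markers, the imprinted RNA MEG3 fell from 115 ± 8.65 to 45.4 ± 6.34 CPM (-1.35 ± 0.15, edgeR adjusted p = 2.07e-05), while AVP (125 ± 18.9 and 115 ± 13.6 CPM) and HLF (5.63 ± 0.54 and 7.27 ± 1.77 CPM), markers of stem cells, were not called. The scaffold protein AKAP12 fell from 2280 ± 263 to 654 ± 55.7 CPM (-1.80 ± 0.17), the transferrin receptor TFRC by 0.85 ± 0.16 on the log2 scale and the interleukin 3 receptor chain IL3RA by 1.02 ± 0.16. GZMB, a protease of cytotoxic and plasmacytoid dendritic cells, fell from 33.7 ± 0.62 to 1.64 ± 0.44 CPM (-4.33 ± 0.31, edgeR adjusted p = 5.45e-08). Counts of members higher and lower by edgeR were 2 and 2 of 14 for stem and multipotent markers and 0 and 1 of 11 for lymphoid markers. They were 0 and 1 of 8 for granulocyte-monocyte, 2 and 1 of 14 for erythroid, 2 and 0 of 7 for megakaryocyte, 0 and 1 of 12 for basophil and mast, and 0 and 2 of 13 for dendritic cell markers. Adjusted over the list alone they were the same except 4 and 1 for megakaryocyte and 3 and 3 for dendritic cell markers. Camera adjusted p for these lists were 0.88, 0.879, 0.222, 0.383, 0.263, 0.637 and 0.561, in that order. With no filter on low counts they were 0.00506 for granulocyte-monocyte and 0.0484 for megakaryocyte markers. Among random lists matched on abundance, the erythroid median of 0.37 lay at percentile 99.69 and the megakaryocyte median of 0.43 at 97.67, both above the middle 95%, and the other 5 lay within it. The erythroid median was 0.007 with library sums thinned to the smallest and 0.14 with each cell thinned to 1000 UMIs, where camera's direction was down. The megakaryocyte median was 0.10 and 0.25 there, and 0.65 without normoxia library 1.

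Other called progenitor markers lost the call when single libraries were left out, while their direction held. Leaving out either hypoxia library also cut the calls over all genes, so a lost call does not tie a marker to that library. MLLT3 (-0.49), HTR1F (0.57), NPR3 (0.63), KLF1 (1.49) and PLEK (0.55) had edgeR adjusted p of 0.127, 0.31, 0.181, 0.27 and 0.213 without hypoxia library 1. Without hypoxia library 2 these were 0.35, 0.103, 0.0799, 0.101 and 0.163, and HTR1F, KLF1 and PLEK had 0.0656, 0.101 and 0.07 without normoxia library 2. CTSG (-1.46) had 0.0711 without hypoxia library 1, and FCER1A (0.84) had 0.0857 without hypoxia library 2.

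Markers of other blood cells were tested too, but many did not pass the filter on low counts. Those tested were 7 of 16 T and NK cell genes and 5 of 10 mature B cell genes. For monocytes and neutrophils they were 3 of 14, and for red cells 2 of 9. Of 7 tested T and NK cell genes 2 fell, GNLY and PRF1, and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.66, the same with GNLY at its bound. That median was -0.002 and -0.36 without normoxia library 1 and hypoxia library 1, and 0.005 with library sums thinned to the smallest. GNLY had 15 UMIs in normoxia and 0 in hypoxia, at least 8.3-fold lower against a floor of 3 counts over the group. PRF1 had 23 and 3 UMIs, a ratio of 0.079 (exact 95% counting interval 0.015 to 0.26). Without hypoxia libraries 1 and 2 their edgeR adjusted p were 0.0655 and 0.0659 for GNLY, and 0.102 and 0.0611 for PRF1. The list's camera adjusted p = 0.0472 became 0.823, 0.184 and 0.515 without normoxia library 1, normoxia library 2 and hypoxia library 1, and an adjusted p = 0.692 with an estimated correlation. It was also lost with library size alone (0.0816) and with cells thinned (0.454), and its median lay at percentile 16.44 of random lists matched on abundance, but at 1.65 without hypoxia library 2. Of 5 mature B cell genes 0 moved (0 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 0.828. Of 3 monocyte and neutrophil genes, MS4A7 and S100A9 fell and CLEC7A rose, the same adjusted over the list alone, with a camera adjusted p = 0.483 and a median at percentile 0.52 of matched random lists, but at 2.78, 3.25, 35.44 and 7.83 without normoxia libraries 1 and 2 and hypoxia libraries 1 and 2. Without normoxia library 1 their edgeR adjusted p were 0.197, 0.102 and 0.261, and without hypoxia library 1 0.104, 0.223 and 0.247; without hypoxia library 2 MS4A7 and CLEC7A had 0.293 and 0.146. Of 2 red cell genes 0 passed (0 and 1 adjusted over the list alone), with a camera adjusted p = 0.383, or 0.0471 without hypoxia library 1.

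The cells were next grouped without the genes called between the conditions, to ask whether cell types differed in share or response. Clusters were named for 338 basophil, eosinophil and mast progenitor-like cells (led by HDC, IL1RL1 and MS4A2, with HBD and ITGA2B among the leading genes), 256 lymphoid progenitor-like cells (MME, JCHAIN and DNTT) and 159 erythroid progenitor-like cells. The erythroid cluster was led by APOC1 and CD36 but also by MPO and by the cell cycle genes PCLAF, TYMS and E2F1. The other 8 clusters stayed unnamed, and the median UMI count of clusters 1 to 5 ran from 491 to 4228 per cell. Shares of the named classes differed by at most 0.66 percentage points, in a test too small to pass 0.05. Basophil, eosinophil and mast progenitor-like cells were 4.36% ± 0.69 of cells in normoxia and 5.02% ± 0.47 in hypoxia (SD over 2 libraries, exact permutation p = 0.667). Lymphoid progenitor-like cells were 3.51% ± 0.38 and 3.66% ± 0.22 (exact permutation p = 0.667), and erythroid progenitor-like cells 1.97% ± 0.15 and 2.499% ± 0.18 (exact permutation p = 0.333, the smallest possible). Unnamed clusters made up 90.2% ± 0.92 and 88.8% ± 0.88 (exact permutation p = 0.333). The erythroid and lymphoid differences, 0.53 and 0.15 percentage points, became -0.12 and -0.29 with the called genes kept in the clustering, where HDC and MS4A2 also led the cluster named erythroid. The lymphoid difference was -0.12 without normoxia library 2 and -0.011 without hypoxia library 2. It was also negative with doublets kept and with at least 500 genes per cell. In the basophil, eosinophil and mast class the difference of 0.66 points became 0.18 and 0.33 without normoxia library 2 and hypoxia library 2. Among cells of at least 1000 UMIs it was 2.02. There HDC and MS4A2 were leading genes of the cluster named erythroid, so the class was not the same. Cluster 7, led by FOS, JUN and HSPA1B, held 8.60% ± 0.82 of cells in normoxia and 3.33% ± 0.34 in hypoxia (exact permutation p = 0.333), but genes that lead it also differed between the conditions.

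Within clusters 1 to 7 and the pooled named classes, the tests were repeated unit by unit. HSPA1A, HSP90AA1 and HES1 were lower in hypoxia in 8 of 8 units by edgeR, with log2 fold changes of -4.08 to -2.83, -2.28 to -1.39 and -3.27 to -1.18. HES4 was lower in 7 of 8, and EGLN3 was higher in 4 of the 4 units where it was tested, by 1.61 to 2.53 (these genes were followed after their values over all cells were seen). EGLN3 was low in normoxia there (4.98 to 11.8 CPM, against 16.5 to 71 in hypoxia), so it could pass the filter through the hypoxia libraries alone. Units with little EGLN3 in both conditions were not tested, so this count does not show that the rise recurred over all units. FOS was lower in 4 of 8 and MYC higher in 2 of 8. Free RNA can add to such a recurrence, since near-empty barcodes (under 150 UMIs) differed too: HSP90AA1 stood there at 7736 and 8021 CPM in normoxia and 2583 and 2787 in hypoxia, and HES1 at 148 and 140 against 39.3 and 76.3. Per near-empty barcode in normoxia, UMIs of HSPA1A, HSP90AA1 and HES1 came to 0.527% to 10.4%, 1.28% to 14.5% and 0.164% to 13.6% of those per cell in clusters 1 to 7. In hypoxia these ranges were 0.512% to 18.4%, 2.25% to 19.1% and 0.796% to 17.3%, and for HES4 they were 0.947% to 9.97% in normoxia and 0.565% to 15% in hypoxia. Heat shock list members fell in each unit, from 7 of 14 in cluster 2 to 11 of 14 in cluster 7. Immediate early genes recurred less: those lower ran from 0 of 9 in cluster 3 to 8 of 20 in cluster 5. In cluster 7 it was 1 of 19, and in some units 1 or 2 members rose. Their medians ran from -0.75 in cluster 5 to -0.21 in the named classes, against -0.89 over all cells. Counts per unit were smaller than over all cells. Among genes of the rule, DCUN1D3 rose in clusters 1 (1.49 ± 0.29) and 2 (2.06 ± 0.27), and MMP9 fell in clusters 1 (-2.96 ± 0.29) and 5 (-3.86 ± 0.36). VGF fell in clusters 4 (-5.30 ± 0.83) and 6 (-4.07 ± 0.62), and GZMB in cluster 6 (-4.19 ± 0.67) and the named classes (-4.63 ± 0.46). In the named classes CH25H, cholesterol 25-hydroxylase, also fell (-4.84 ± 0.61), and MAML1 rose (1.73 ± 0.45). The rule names only 3 genes per direction and unit, so these changes need not be confined to the units given. Among other genes followed, GZMB was lower in 5 of 5 tested units, TIMP3 in 6 of 7 and DNAJB1 in 3 of 7. GZMB was near 0 CPM in hypoxia, so it could pass the filter through the normoxia libraries alone. Summed over the 8 units, edgeR made 1249 calls higher and 1876 lower, against 152 and 347 by DESeq2. Leaving out normoxia library 1, hypoxia library 1 or hypoxia library 2 gave 830 and 1060, 308 and 635, or 242 and 552.

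**Figure D3:**
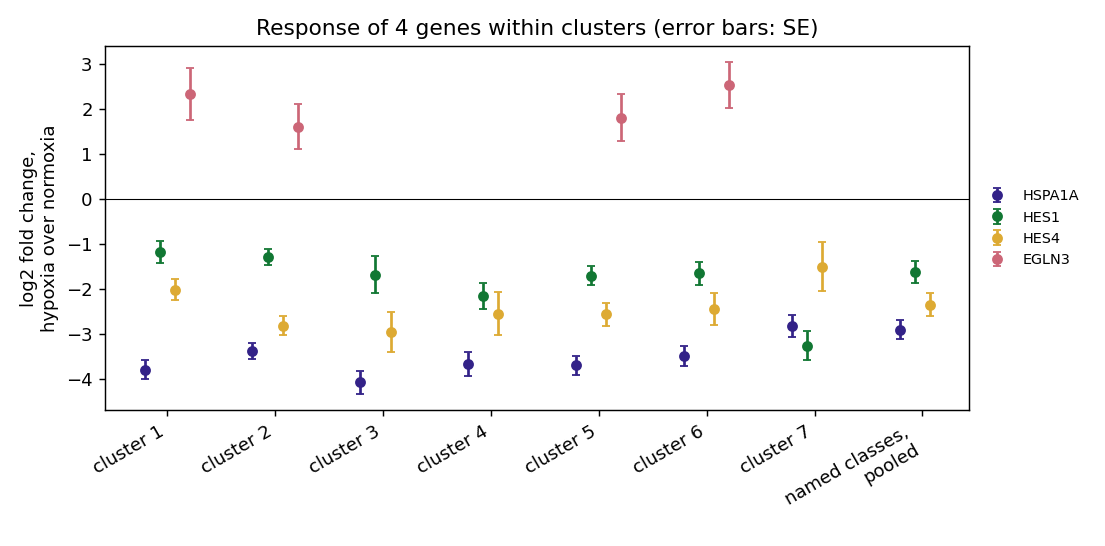
Log2 fold change (hypoxia over normoxia) of 4 genes within clusters 1 to 7 and the pooled named classes. Error bars are the SE derived from the edgeR fold change and F statistic. A gene without a point was not tested there. HSPA1A, HES1 and HES4 lie below 0 in each unit and EGLN3 above 0 in the 4 units where it was tested. Units with little EGLN3 in both conditions did not pass the filter on low counts.

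The response was then compared between clusters. Over 7 comparisons with cluster 1, the interaction test made 31 calls at an edgeR adjusted p under 0.05, some genes being called in more than 1 comparison, and 23 of the calls were in cluster 7, the cluster led by FOS, JUN and HSPA1B. Clusters 2 and 3 had 0 calls by edgeR, with 595 of 11063 and 248 of 5716 tested genes at an unadjusted edgeR p under 0.05. These are close to the share of 0.05 that no difference would give. No other tool was run on this test. The sum was 16 without normoxia library 1 and 13 without hypoxia library 2.

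At a fixed depth of 1000 UMIs per cell, cells had 699 ± 15.4 genes in normoxia and 688 ± 3.93 in hypoxia (SD over 2 libraries; 874 and 705 cells left out), a gap smaller than the SD in normoxia. Without thinning, and with the shallower cells back, the values were 1160 ± 221 and 1454 ± 35.9 genes.

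The other fixed lists had camera adjusted p above 0.05. Of 16 NF-kB and cytokine response genes 1 rose and 3 fell (the same adjusted over the list alone), among them PTGS2, the inducible cyclooxygenase, from 83.4 ± 10.3 to 33.4 ± 1.23 CPM (edgeR adjusted p = 3.93e-05). Their median was 0.081, but -0.045 when scaled by library size alone and 0.12, -0.11, -0.017 and -0.14 without normoxia libraries 1 and 2 and hypoxia libraries 1 and 2. Their mean was -0.20. The other calls were CCL4 (-2.45, uncertain because of the near-identical CCL4L2), TNFAIP3 (-0.87) and NFKBIA (0.50), with edgeR adjusted p of 0.301, 0.0784 and 0.355 without hypoxia library 2; without hypoxia library 1 TNFAIP3 and NFKBIA had 0.192 and 0.0862. Of 20 MYC and ribosome biogenesis genes 1 rose and 2 fell (3 and 2 adjusted over the list alone), among them the polyamine enzyme ODC1, from 106 ± 6.07 to 41.7 ± 5.35 CPM (edgeR adjusted p = 2.44e-05). RRP9 (-0.99) and NPM1 (0.57) had edgeR adjusted p of 0.277 and 0.0768 without hypoxia library 1, and NPM1 0.182 without hypoxia library 2. The median of that list was -0.042, at percentile 1.78 of random lists matched on abundance, but 0.093 without normoxia library 1 (percentile 10.33) and 0.058 without hypoxia library 1 (7.18). Without normoxia library 2 and hypoxia library 2 it was -0.084 and -0.11. Of 12 STAT5 and cytokine receptor targets, the feedback inhibitors SOCS3 (0.70 ± 0.15) and CISH (0.70 ± 0.15) rose and SOCS2 (-0.48 ± 0.13) and OSM (-0.60 ± 0.17) fell (4 and 3 adjusted over the list alone). Without hypoxia library 2 the edgeR adjusted p of SOCS3 and CISH were 0.0905 and 0.1, and those of SOCS2 and OSM 0.179 and 0.112; without hypoxia library 1 SOCS2 and OSM had 0.29 and 0.286. The median was -0.088, but -0.19, 0.036, -0.046 and -0.055 without normoxia libraries 1 and 2 and hypoxia libraries 1 and 2, and the mean was 0.008. Members higher and lower were 1 and 1 of 13 for NRF2 and oxidative stress, 0 and 2 of 14 for p53 targets and 0 and 1 of 18 for interferon response, the same adjusted over the list alone. Those calls were TXNRD1, SLC7A11, FAS, XPC and XAF1. Without hypoxia library 2, TXNRD1, SLC7A11, XPC and XAF1 had edgeR adjusted p of 0.262, 0.157, 0.116 and 0.151. Without hypoxia library 1, TXNRD1, SLC7A11, FAS and XPC had 0.252, 0.0599, 0.114 and 0.147, and without normoxia library 1 TXNRD1, FAS and XPC had 0.0636, 0.0563 and 0.11. Camera adjusted p for NF-kB, MYC, STAT5, NRF2, p53 and interferon were 0.593, 0.88, 0.88, 0.54, 0.637 and 0.88.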

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

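The tests by cluster number, the counts in near-empty barcodes and the tests of a stressed subset of cells and of another difference between the experiments were chosen after the results were seen. Genes whose response differed from that in cluster 1, the largest cluster, are given first as differences in log2 fold change with edgeR interaction adjusted p. In cluster 4 the growth factor HBEGF had -1.28 (0.0421), and in cluster 5 the feedback inhibitor SOCS3 had -0.92 (0.0486). Cluster 4 had 0 calls without any 1 of the 4 libraries, with no filter and with at least 500 genes per cell. Cluster 5 had 0 calls without either hypoxia library, with RLE size factors and with no filter. In cluster 6 the chaperone HSP90AA1 had 0.44 (7.95e-11), CYP1B1 -0.51 (0.0253), SOCS3 -0.95 (0.0253) and SECTM1 -1.64 (0.031). The 4 lower calls of cluster 6 became 0 without normoxia library 1, hypoxia library 1 or hypoxia library 2. In cluster 7, led by FOS, JUN and HSPA1B, the leukotriene receptor CYSLTR2 had -2.36 (0.0212), ZFAND2A -2.17 (0.0303) and the cytokine OSM -2.60 (0.0454). In the same cluster the linker histone H1FX had 1.22 (0.0303), KCNQ1OT1 1.32 (0.0446) and CALM1 1.10 (0.0454). Its 10 higher and 13 lower calls became 7 and 6 without normoxia library 1, 5 and 10 without normoxia library 2, 6 and 15 without hypoxia library 1, and 8 and 3 without hypoxia library 2. In the pooled named classes the chemokine CXCL3 had 2.94 (0.00138), but the unit had 0 calls without normoxia library 1, normoxia library 2 or hypoxia library 1. Also in cluster 7, and chosen after their values were seen, HES1 had -1.94 ± 0.32 (0.000189). There the chaperones called, also chosen after their values were seen, went both ways: HSPA1A had 1.03 ± 0.18 (0.000352) and HSP90B1 0.78 (0.00106), but DNAJB1 -1.51 (0.0141), HSPA8 -1.21 (0.0022), HSPB1 -1.04 (0.0419) and HSP90AA1 -0.37 (0.0311).

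Barcodes with under 150 UMIs, which were left out of the kept cells, held HSPA1A too. They had 138 and 108 HSPA1A UMIs in the normoxia libraries and 8 and 7 in the hypoxia libraries. As a level these are 928 and 1163 CPM against 1274 and 1532 CPM in the kept cells of normoxia, and 105 and 59.3 CPM against 112.7 and 102.7 CPM in hypoxia.

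Heat shock genes were lower in hypoxia by a median log2 fold change of -1.21. A stressed subset of cells as the whole cause would leave a median closer to 0 than 0.5 times that value once the cluster led by stress genes is left out, but the median there was -0.92, with 9 of 14 members still lower. Damaged cells with a high mitochondrial share as the whole cause would do the same among the cells with the lower share, but the median there was -1.32. The cluster led by stress genes was drawn without the called genes, so stressed cells may lie outside it, and its removal tests that cluster only. In cells with no UMI of 11 stress genes the median was -0.16, with 5 of 12 members lower. HSPA1A and HSPA1B are among those 11 genes, so that choice of cells depends on the list itself and decides nothing. Another difference between the experiments and an effect of oxygen or ligand dose cannot be told apart, since 0 experiments had libraries of both conditions. An effect of oxygen or dose therefore stays open and untested.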

How the results depend on the processing

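Removal of the cluster led by stress genes, the crossed block and all tests by cluster were chosen after the data were seen. Of 93 called named genes, 50 kept direction and call under every alternative run, 43 lost the call under at least 1, and 0 reversed. The causes below were not tested unless stated. For 1113 genes higher and 1133 lower (170 and 669 at least 2-fold), library size alone gave 514 higher (86 at least 2-fold), and DESeq2 548 and 451 (88 and 289). No filter on low counts gave 268 at least 2-fold higher. Thinned library sums gave 619 higher (109 at least 2-fold), and cells thinned to 1000 UMIs 445 and 582 (96 and 402), with fewer genes tested, 12749 and 11891 of 16449. Without each library in turn, the counts ran from 301 to 1484 higher, 412 to 1392 lower, 121 to 356 at least 2-fold higher and 344 to 715 at least 2-fold lower. Without the cluster led by stress genes they were 1013 and 1084.

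With an estimated correlation, camera no longer called glycolysis (0.406, adjusted p = 0.692), immediate early genes (-0.889, 0.431) or heat shock genes (-1.211, 0.431), nor any of the other lists it had called. That version has 2 residual degrees of freedom, and its lowest unadjusted camera p of any list was 0.0319, for heat shock genes. It therefore had little power to call a list. Fry lost 7 lists, glycolysis (adjusted p = 0.173), respiratory chain, mitochondrial, ribosomal, ATF4, cholesterol, and T and NK cell genes, and gained monocytes and neutrophils. HIF targets were called with no filter on low counts (0.234, adjusted p = 0.0268). Notch targets were called without any 1 library, with medians from -0.232 to -0.027. Without single libraries, medians ran from 0.163 to 0.201 for HIF targets, 0.301 to 0.541 for glycolysis, -1.252 to -1.145 for heat shock and -0.885 to -0.836 for immediate early genes. Limma-voom gave the lists the same values by construction. Library size alone turned the sign of the medians of 4 lists, none of them called: stem and multipotent markers (also turned without mitochondrial and ribosomal protein genes), NF-kB, NRF2 and interferon. The same scaling shifted the median of all genes by -0.128. It lowered the medians of HIF targets from 0.173 to 0.044, of cholesterol synthesis from 0.217 to 0.083 and of Notch pathway components from 0.245 to 0.123. Over all lists, 510 values under an alternative kept direction and side of the threshold, 11 gained a call and 33 lost one.

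With the replicate number as a block, the counts were 1004 and 1143, and the call of Notch targets appeared (-0.046, camera adjusted p = 0.00455). Deviations of libraries with the same number correlated at -0.289 over 3623 genes, and the labels do not say that a number pairs runs. A crossed block, fitted only because that correlation was negative, gave 1892 and 1704. Crossed numbers correlate at 0.289 by construction, so this block was picked from the same data and its higher counts do not show that runs are paired.

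Within clusters, 1249 calls higher and 1876 lower became 1158 lower with no filter and 152 and 347 by DESeq2. Without each library in turn they ran from 242 to 1225 and 552 to 1611, and the 31 interaction calls from 13 to 22. Differences in share (percentage points) were 0.66 for basophil, eosinophil and mast, 0.53 for erythroid, 0.15 for lymphoid and -1.34 for unnamed clusters. With cells of at least 1000 UMIs these were 2.024, 0.091, 0.534 and -2.649. There HDC and MS4A2 were leading genes of the cluster named erythroid, so the first and second values are not for the same classes. With called genes kept in the clustering, the last 3 were -0.119, -0.287 and 0.407, again with HDC and MS4A2 leading the cluster named erythroid. At resolution 0.5 the first was 1.328. That cluster was also led by APOC1, CD36 and GATA1, leading genes of the main erythroid cluster, so it was not the same class either. No cluster was named erythroid at resolution 0.5 or with doublets kept, nor basophil, eosinophil and mast with called genes kept, so those gave no value. Without each library in turn they ran from 0.177 to 1.147, 0.4 to 0.66, -0.123 to 0.418 and -1.992 to -0.687. The gap in genes per cell was 293.26 without thinning, which also brought back the 1579 cells under 1000 UMIs, and -21.26 to 0.47 without single libraries. As for depth, both kinds of thinning gave fewer calls, and the simulated data did not vary it.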

Other observations

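The tests of the ligand dose and of HES4 by cluster and the genes of this paragraph other than GZMB were chosen after the results were seen. Counts of single genes are given without a test of a group, and the intervals cover counting error only. The interleukin 2 receptor chain IL2RA had 207 UMIs in normoxia and 38 in hypoxia, a ratio of 0.111 (exact 95% counting interval 0.076 to 0.157), and the kinase ITK had 123 and 31, a ratio of 0.152 (0.099 to 0.227). The chemokine CCL4L2 had 74 and 5 UMIs, which is uncertain, since reads of the near-identical CCL4 (26 and 7 UMIs) cannot be told from its own. NKG7, a cytotoxic granule gene, had 153 and 140, which at the deeper hypoxia libraries is a ratio of 0.551 (0.435 to 0.698). CCL5 had 9 and 5 UMIs (ratio interval 0.088 to 1.112), CD3D 3 and 1, CD3E 1 and 6, CD3G 0 and 2, and TRAC 7 and 6. GZMB had 239 UMIs in normoxia and 18 in hypoxia, a ratio of 0.045 (exact 95% counting interval 0.026 to 0.073). Of its UMIs in clustered normoxia cells, 77 of 237 (32.5%) lay in the basophil, eosinophil and mast progenitor-like cluster.

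HES1 and HES4 were lower in hypoxia, with log2 fold changes of -1.99 and -2.39. Stress activation of the kind that marks cluster 7, led by stress genes, needs more HES4 there. In normoxia the CPM of HES4 in cluster 7 was instead 0.523 times that in the other clusters. Exact 95% counting intervals were 0.341 to 0.708 and 0.338 to 0.925 in the 2 libraries. But HSPA1A was lower in hypoxia in 8 of 8 units (1266 and 90.1 CPM in cluster 1), so the other normoxia clusters were no unstressed reference. The ratio therefore cannot decide on stress shared by all normoxia clusters. In cells with no UMI of 11 stress genes HES4 had -2.39 ± 0.25. The CPM of HES1 in cluster 7 was 6.73 times that in the other clusters; cluster 7 held 37.5% of its normoxia UMIs, and HES1 had -1.37 ± 0.22 in the cells with no UMI of the stress genes, past the bound of 0.5 times its value set beforehand. But the cells with no UMI of the stress genes still differed in stress (HSPH1 -1.33 in place of -2.09, HSP90AA1 -1.23, 5 of 12 heat shock genes lower) and in median depth (867 and 616 UMIs in normoxia, 1726 and 1833 in hypoxia). The reading for HES1 was therefore left open after these values were seen, and the HES4 value in these cells decides nothing either. For HES1, and for HES4 where stress is shared by all clusters, stress activation and other causes cannot be told apart. A lower ligand dose and an effect of oxygen, which stays untested, cannot be told apart either, since 0 ligand doses were used in both conditions.

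Of glycolysis genes 3 of 16 and of nuclear respiratory chain genes 4 of 32 rose in hypoxia and 0 fell. Both list calls had an adjusted p = 0.692 in camera with an estimated correlation, a test with little power here. Over all tested genes, median log2 fold changes went from -0.24 in the lowest to 0.29 in the highest of 6 bins of abundance. Against 10000 random lists matched on abundance, the glycolysis median lay at percentile 99.63 and the respiratory chain median at 98.97, both past the bound set beforehand, the upper end of the middle 95%. The reading was left open afterwards, when percentiles without single libraries were seen: glycolysis had 96.69 without hypoxia library 2, and the respiratory chain had 95.31, 87.19 and 57.3 without normoxia library 1, normoxia library 2 and hypoxia library 2. A shift of all abundant transcripts and a change in these pathways therefore cannot be told apart.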
